A study of Mus musculus with 10 samples.

How the data were processed

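ATAC-seq, in which a transposase cuts accessible DNA and tags the ends for sequencing, was applied to 10 libraries of mouse bone marrow stromal cells of strain C57BL/6J. Per the labels' protocols, 2700 to 5000 cells were sorted per library, transposed for 30 minutes at 37 °C, amplified for 13 or 17 PCR cycles and sequenced as read pairs of 100 bp on an Illumina HiSeq instrument. Per the labels, 2 libraries came from freshly sorted Scf-GFP-negative stroma, 2 from freshly sorted Scf-GFP-positive stroma, 3 from cultured stroma transduced with a control vector and 3 from rMSC, the submitters' name for cultured stroma transduced with Klf7, Ostf1, Xbp1, Irf3 and Irf7. The labels do not state that replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Flow cell names in the deposited data place replicate 1 of every group on flow cell AHY33MBCXX and the other libraries on AC99CPACXX, so flow cell and group are not confounded.

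Per the submitters' processing notes, BWA, MACS2 and the mm10 build were used; versions and settings are not given in the sources used here. The deposited data are peak lists, 1 per library, called by the authors on each library alone. Each peak carries the authors' fold enrichment, a ratio of the summit pileup to the caller's background, the −log10 of a p-value and of a q-value, and a deposited score equal to 10 times the −log10 q without decimals. The lowest deposited −log10 q was 1.313. These values are the authors' and were used only to describe, rank or filter peaks within a list. Read counts per library were not used here, so sequencing depth is unknown. The fold values let part of it be recovered. In every list 100% of summit pileups came out whole within 0.01, over a constant background of 0.236 to 0.715 fragments, and the weakest peaks rested on 3 to 5 fragments. A site missing from a list can therefore be open and undetected, and absence is stated only for the list.

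Peaks on chromosomes 1 to 19 and X were used, and those on chromosome Y were set aside. Because list length differed, the comparisons used equal-size lists, the 39912 peaks of each library with the highest −log10 p. Equal size does not level peak strength. The lowest −log10 q in these lists was 2.653 and 2.097 in Scf-GFP-negative replicates 1 and 2 and 4.268 to 5.802 in the other libraries. Loci and regions absent from or particular to Scf-GFP-negative lists carry this limit. Gene positions came from a RefSeq gene table of GRCm38.p6, which has mm10 coordinates, and all coordinates are 1-based mm10. For each of 21631 protein-coding genes, peak summits were counted in the locus, defined as the gene body with 10 kb on either side. A locus can hold summits of a neighbouring or overlapping gene (Timp3 lies inside another gene), so a count belongs to the locus and not to 1 promoter. Loci with a mean of at least 2 summits per library were tested, which left 9148. The mean is over all libraries, so a locus open in a single group can be left out. List counts below refer to tested members. The value log2(summits + 0.5) was fitted with limma with a trend (limma 3.58.1, R 4.3.3) for all 4 groups in 1 fit, which share 1 estimate of the spread, with 6 residual and 1.538 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 9148 loci of a comparison, with a threshold of 0.05, and are two-sided. Log2 changes are on the log2(summits + 0.5) scale with their standard error (SE), and this scale understates changes of loci with few summits. Where the compared group had no summit in any library, summit counts are given without a fold. On simulated summit counts for the 9148 loci, with 100 loci changed by each fold, the fit recovered 10 of the 4-fold and 0 of the 2-fold changes for Scf-GFP-positive against Scf-GFP-negative. It recovered 32 and 5 for control against Scf-GFP-positive, 54 and 1 for rMSC against control, and 39 and 0 for rMSC against Scf-GFP-positive. At most 3 of 8948 unchanged loci were called. The simulated counts had Poisson spread alone and fewer changed loci than were called in the data. Neither the recovery nor the rate of false calls therefore carries over to these data. A locus that did not pass can still differ.

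The genes to be named were set by a rule. For each of the 4 comparisons it takes the 10 loci with more and the 10 with fewer summits that passed, did not overlap between the groups in any library and had the largest log2 change. Numbered clones and olfactory or vomeronasal receptors were excluded, and of genes within 50 kb of one another 1 was kept. It adds up to 4 passing members of each gene list per direction, the 5 transduced genes, and Kitl, Cxcl12, Vcam1 and Angpt1 whatever their p. The rule named 248 gene and comparison pairs, of which 215 passed. The text gives values for part of them, picked from the rule's genes after their values were seen and favouring loci whose call did not rest on 1 library. Of all 215, 113 kept the call in every fit that left out 1 library and still tested the locus. A locus that fell below the summit filter in such a fit was not tested there and was not counted as a lost call. The 20 gene lists held 381 members, of which 5 had no gene in the annotation. They covered the transduced factors, niche factors, mesenchymal, osteoblast, adipocyte, chondrocyte and fibroblast lineages, interferon, unfolded protein, AP-1, cell cycle and senescence genes. The rest were markers of cell types the gate could hold (lymphoid, myeloid, erythroid and megakaryocyte, endothelial, Schwann, smooth muscle), ubiquitously open promoters and genes of other organs. Each list was tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 20 lists, and again with an estimated correlation.

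Similarity between libraries was the base-pair Jaccard index, the length shared by 2 lists over the length covered by either. Freshly sorted and cultured libraries were compared by the mean index within minus between these classes over all 210 groupings of 4 against 6 libraries, one-sided. Overlapping peaks of all libraries were merged into 117536 union regions, and a region was open in a library where any of its peaks overlapped it. Culture-lost regions were open in both Scf-GFP-positive libraries and in neither of a pair of control libraries, and the share open was measured in the left-out control library and in each rMSC library. Culture-gained regions were open in the pair of control libraries and in neither Scf-GFP-positive library. Because regions chosen on control libraries favour a difference in any other group, they were also chosen on pairs of rMSC libraries. Values of 3 against 3 libraries were compared by exact permutation tests, two-sided unless stated, whose smallest p is 0.1 (0.05 one-sided). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The interval operations passed 4 of 4 tests on simulated intervals.

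The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. These alternatives were all deposited peaks, a −log10 q of at least 5, a 50 kb window, a pseudocount of 1, no filter, no trend, the replicate number as a block, the flow cell as a covariate, only the 2 groups compared, at least 50% of a region covered, and each library left out in turn. Chosen after seeing the data were a window within 5 kb of either gene end, equalised chromosome totals, regions over 1 kb from any gene end, leaving out chromosomes 4, 10 and 15, the mirror choice of culture regions on rMSC, and the share of each transduced gene's body covered by all deposited peaks. Motif shares and peaks over exons were planned and not run, and windows around transcription start sites were replaced by gene ends, because sequence, exons and strand were not used here.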

Results

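Scf-GFP marks stromal cells that express stem cell factor, encoded by Kitl, a ligand that blood stem cells need. The 10 libraries hold Scf-GFP-negative stroma (n = 2), Scf-GFP-positive stroma (n = 2), cultured stroma with a control vector (n = 3) and rMSC (n = 3), cultured stroma that received Klf7, Ostf1, Xbp1, Irf3 and Irf7. Both cultures were seeded from Scf-GFP-positive stroma in medium with 20% serum and FGF-basic. The deposited lists held 46947 and 39936 peaks in Scf-GFP-negative stroma, 47679 and 68298 in Scf-GFP-positive stroma, 48417, 75376 and 72791 in control cultures, and 66282, 70975 and 78489 in rMSC. They covered 20.9 to 33.7 Mb of the genome. In lists of equal size, 29.5 ± 0.707% (mean ± SD) of peaks in Scf-GFP-negative and 30.2 ± 0.396% in Scf-GFP-positive stroma lay near gene ends, against 26.6 ± 0.720% in control cultures and 26.8 ± 0.207% in rMSC.

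Libraries were on average more alike within than between freshly sorted and cultured stroma. The mean Jaccard index, the share of covered bases common to 2 libraries, was 0.167 higher within than between these classes (permutation p = 0.00476, one-sided, the smallest possible with 210 groupings, n = 4 and 6). The real grouping is the only one that keeps all 4 groups whole, so likeness of replicates lowers this p as well. The difference was 0.164 among the libraries of flow cell AC99CPACXX (permutation p = 0.0667, 15 groupings) and 0.0834 on AHY33MBCXX, with 1 library per group (permutation p = 0.333, 6 groupings). Control cultures and rMSC shared 0.432 of covered bases, less than the 0.558 within control and 0.578 within rMSC. Scf-GFP-positive stroma shared 0.344 with control cultures, 0.331 with rMSC and 0.312 with Scf-GFP-negative stroma. It was closer to the cultures seeded from it than to the other sorted stroma, so the sorted libraries formed no class. The class difference thus mixes sorting with Scf-GFP status. The caller's background also followed the classes, at 0.391 to 0.715 fragments in sorted and 0.236 to 0.353 in cultured libraries. Scf-GFP-negative stroma stood furthest from the cultures, at 0.234 for control and 0.242 for rMSC, and its replicates were the least alike (0.457, against 0.541 in Scf-GFP-positive stroma). Its equal-size lists also held weaker peaks, down to a −log10 q of 2.653 and 2.097, against 4.268 or more in every other library. Merging all lists gave 117536 regions, of which 9444 were open in all 10 libraries and 50651 in 1 alone.

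**Figure D1:**
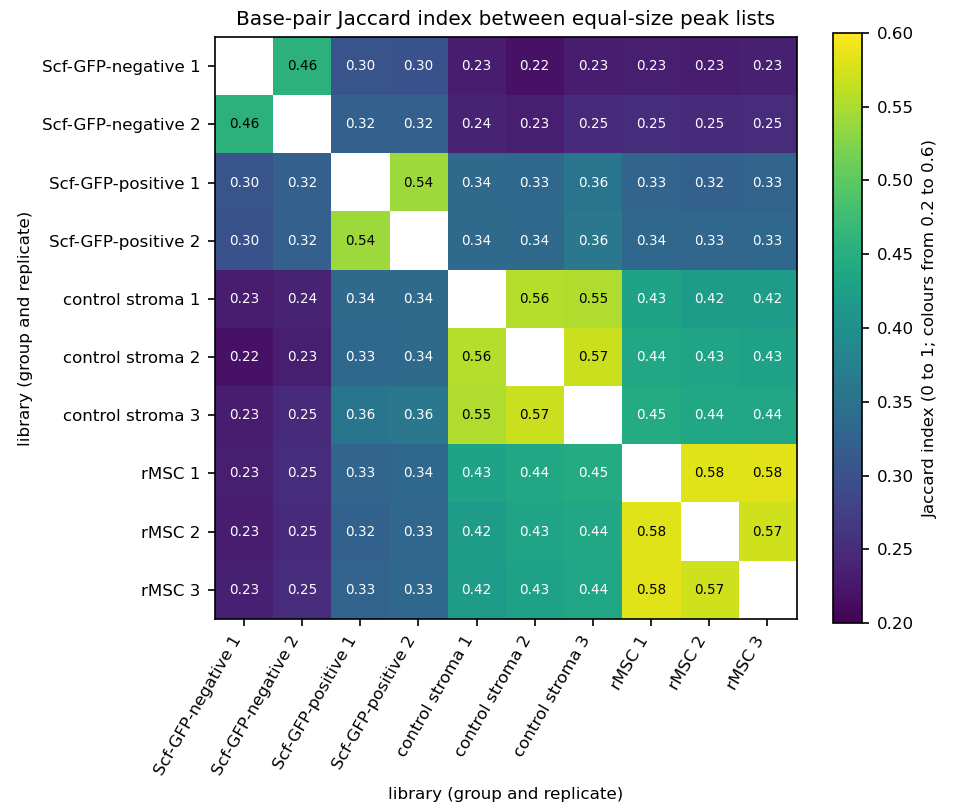
Base-pair Jaccard index between the equal-size peak lists of all library pairs.

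Scf-GFP-positive stroma carried peaks at many loci that had few or none in Scf-GFP-negative stroma. Fndc3b, a fibronectin-domain gene (Gene 72007, chromosome 3, 27416135 to 27711307), had 21.0 ± 1.41 summits in Scf-GFP-positive and none in Scf-GFP-negative libraries (limma adjusted p = 1.46e-06, n = 2 and 2). Pknox2 (20.0 ± 2.83), Dlc1 (17.5 ± 0.707) and Palld (16 ± 1.41) were likewise at 0 in Scf-GFP-negative stroma, as was Prrx1, a limb mesenchyme regulator, with 6.5 ± 2.12. Locus Alpl, the bone alkaline phosphatase (Gene 11647, chromosome 4, 137741731 to 137796384), rose by log2 3.53 ± 0.49 (SE), from 0.5 ± 0.707 to 9.50 ± 0.707 summits (adjusted p = 0.00211). The parathyroid hormone receptor Pth1r (chromosome 9, 110722085 to 110747145) rose by log2 2.87 ± 0.33 (adjusted p = 0.000849). These p-values use the spread shared by all 4 groups and not that of the compared libraries alone. With only the 2 groups fitted, 30 of 80 named calls of this comparison were kept.

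In the niche factor list 11 of 16 tested loci rose and 0 fell at the genome-wide threshold, and 11 and 0 adjusted over the list alone (list adjusted p = 0.00029, with an estimated correlation adjusted p = 0.0385). Csf1, the macrophage growth factor, rose by log2 3.06 ± 0.52 (adjusted p = 0.00478), Il34, a ligand of the same receptor, by 3.21 ± 0.44 (adjusted p = 0.00191), and Pdgfa went from 0 to 4.00 ± 1.41 summits (adjusted p = 0.000145). Kitl itself (chromosome 10, 100015615 to 100100416) rose by log2 2.41 ± 0.64 (adjusted p = 0.0266), but not without Scf-GFP-negative replicate 2 (log2 1.62, adjusted p = 0.137) or Scf-GFP-positive replicate 1 (1.53, adjusted p = 0.129). Cxcl12, the chemokine that retains blood stem cells, rose by log2 1.77 ± 0.51 (adjusted p = 0.0357), a call lost without any of 7 libraries (adjusted p = 0.157 at most, without Scf-GFP-positive replicate 2), with log2 changes from 0.98 without Scf-GFP-negative replicate 2 to 2.57 without replicate 1. Angpt1, another niche factor, did not pass (log2 −0.28 ± 0.20, adjusted p = 0.333), and Vcam1 had too few summits to be tested.

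The osteoblast list rose with 6 of 8 loci and 0 falling, the same counts adjusted over the list alone (list adjusted p = 0.00029, with an estimated correlation adjusted p = 0.0385). Examples are Col1a1, the main bone collagen (log2 2.80 ± 0.28, adjusted p = 0.000493), Alpl and Pth1r. Of 18 fibroblast and myofibroblast loci 10 rose and 1, Itga5, fell, with 10 and 2 adjusted over the list alone (list adjusted p = 0.000358, with an estimated correlation adjusted p = 0.0385). The matrix crosslinker Lox went from 0 to 4.50 ± 2.12 summits and the matrix protein Ccn1 from 0 to 7.0. Of 17 mesenchymal loci 8 rose and 0 fell, with 9 and 1 adjusted over the list alone (list adjusted p = 0.00171, but with an estimated correlation adjusted p = 0.318). The stromal transcription factors Ebf1 (chromosome 11, 44618100 to 45008096, log2 2.43 ± 0.17, adjusted p = 8.95e-05) and Ebf2 (2.52 ± 0.45, adjusted p = 0.00581) were among them. Smooth muscle and pericyte loci rose at 3 of 5 and fell at 0, with 4 and 1 adjusted over the list alone (list adjusted p = 0.00994, with an estimated correlation adjusted p = 0.108). They include Lmod1 (log2 2.64 ± 0.46), Mylk, from 0 to 13.5 ± 0.707 summits, and Tbx18, from 0 to 5.50 ± 0.707.

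Cell cycle loci fell at 5 of 15 and rose at 0, with 6 falling adjusted over the list alone (list adjusted p = 0.0478, but with an estimated correlation adjusted p = 0.160 and with equalised chromosome totals 0.0770). Among them were Mki67, a marker of dividing cells (log2 −2.06 ± 0.41, adjusted p = 0.00871), and Mcm6, a replication helicase gene (−1.22 ± 0.20, adjusted p = 0.00441). Some blood cell loci had more summits in Scf-GFP-negative stroma, although the gate excluded CD45 and Ter119. Ptprc, which encodes CD45, had 5.00 summits in each Scf-GFP-negative library and none in Scf-GFP-positive ones (adjusted p = 0.00012). The lymphoid regulator Ikzf1 (chromosome 11, 11684962 to 11772930) fell by log2 1.98 ± 0.30 (adjusted p = 0.00304), and the erythroid regulator Klf1 fell by 0.85 ± 0.13 (adjusted p = 0.00281). The blood marker lists as a whole did not pass: pan-haematopoietic 1 (Ebf1) rose and 3 fell of 13 (list adjusted p = 0.737), myeloid 1 (Elane) and 2 of 4 (0.629), and erythroid and megakaryocyte 0 and 2 of 7 (0.0724). The filter left 13 of 22 pan-haematopoietic, 4 of 20 myeloid and 7 of 19 erythroid and megakaryocyte members. It can remove loci open in Scf-GFP-negative stroma alone, so these list results cannot exclude blood cells there.

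The other lists did not pass. Adipocyte loci rose at 3 and fell at 1 of 7 (list adjusted p = 0.514, but 0.0107 with all deposited peaks), with the fat-cell regulator Zfp423 up by log2 3.85 ± 0.44 (adjusted p = 0.00093) and Adipor2 down by 1.65 ± 0.18. Chondrocyte loci rose at 3 and fell at 1 of 6 (0.514), AP-1 loci at 6 and 2 of 21 (0.0724), interferon loci at 1 and 1 of 12 (0.833), unfolded protein loci at 1 and 3 of 20 (0.635), senescence loci at 0 and 3 of 8 (0.612) and Schwann loci at 2 and 3 of 8 (0.796). No locus passed among the 5 tested of 18 endothelial members (0.844), the 2 tested of 20 other-organ members (0.833) or the 5 transduced genes (0.737). Ubiquitously open loci fell at 4 of 14 (0.153), among them Gapdh (log2 −2.04 ± 0.26, adjusted p = 0.00139). Genome-wide, 1263 loci had more and 1600 fewer summits in Scf-GFP-positive stroma, and the median shift over all tested loci was log2 −0.24. The balance rests on Scf-GFP-negative replicate 2, since 1349 rose and 1096 fell without it. Chromosome 6, where Scf-GFP-negative replicate 1 has an excess of weak peaks, held 145 falling loci of 475 tested, and 69 after chromosome totals were equalised. Chromosome 5 held 152 of 556, and 86 after equalising. Regions open in both libraries of one group and neither of the other numbered 11668 for Scf-GFP-positive and 5456 for Scf-GFP-negative stroma. Without replicate 1 the Scf-GFP-positive regions were 20067, without replicate 2 they were 19841, and the Scf-GFP-negative regions were 18476 and 19937 without each of their own replicates, so the region numbers depend on having 2 libraries. The strongest Scf-GFP-positive regions lay in Pdk4 (chromosome 6, 5495799 to 5497205) and in Wwtr1, the gene of the mechanosensing cofactor TAZ (chromosome 3, 57574743 to 57577047), both also open in every culture, and 13376 bp from Ssu2 (chromosome 6, 112401575 to 112402853). Strongest for Scf-GFP-negative stroma, and open in no other library, were regions in Rfx2 (chromosome 17, 56826513 to 56828195), 1866 bp from Fam117a (chromosome 11, 95333537 to 95335152) and 4821 bp from Inka2 (chromosome 3, 105698864 to 105699778).

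**Figure D2:**
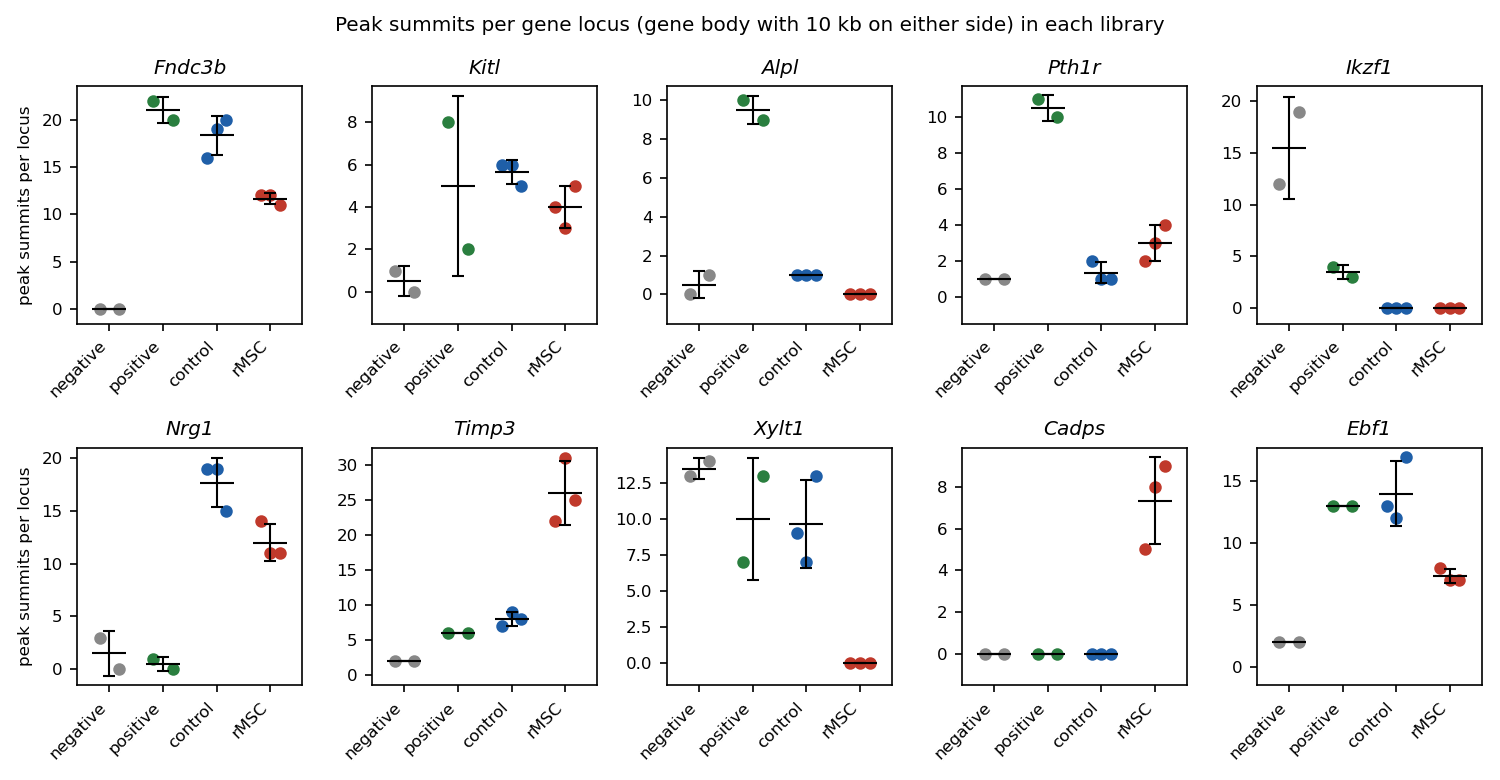
Peak summits per library, with group mean and SD, at 10 loci.

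Cultured stroma with the control vector had fewer summits at some bone-lineage loci than Scf-GFP-positive stroma. Alpl fell by log2 2.74 ± 0.45, from 9.50 ± 0.707 to 1.00 summits (adjusted p = 0.0121, n = 2 and 3), and Pth1r by 2.63 ± 0.30 (adjusted p = 0.00286). The osteoblast list fell at 3 of 8 loci (Sp7, Alpl, Pth1r) and rose at 0, with 6 falling adjusted over the list alone (list adjusted p = 0.0177, but with an estimated correlation adjusted p = 0.342). St3gal6, a sialyltransferase, and Sema4d each lost all of 12.5 summits, and Ikzf1 lost all of 3.50 ± 0.707. The stromal smooth muscle regulator Tbx18 fell by log2 2.00 ± 0.20 (adjusted p = 0.00149), Runx1 by 1.00 ± 0.14 (adjusted p = 0.00712), Fry by 3.20 ± 0.23 (adjusted p = 0.000449) and Bcl11a by 3.62 ± 0.49 (adjusted p = 0.00564). The pericyte receptor Notch3 fell by 2.23 ± 0.38 (adjusted p = 0.0134), but not without Scf-GFP-positive replicate 1 (adjusted p = 0.0738).

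Other loci opened in culture. Nrg1, a growth factor gene (chromosome 8, 31807452 to 32891609), had 1 and 0 summits in Scf-GFP-positive stroma and 19, 19 and 15 in control cultures (log2 4.38 ± 0.77, adjusted p = 0.0148, but 0.0801 without Scf-GFP-positive replicate 2). Slc7a14 rose from 0 to 7.0 ± 2.00 summits, the heat shock gene Hspb8 from 0 to 5.00, the interleukin receptor Il1rl1 from 0 to 5.00 ± 1.00, and the blood markers Itgb2 and Ptprc from 0 to 3.00 and 1.67. Kitl (log2 0.42, adjusted p = 0.708) and Cxcl12 (0.20, adjusted p = 0.860) did not change detectably. No other list passed. Niche factors rose at 2 (Ccl2, Thpo) and fell at 1 (Fgf1) of 16 (list adjusted p = 0.994), mesenchymal loci at 1 (Cd44) and 1 (Zeb2) of 17 (0.761), fibroblast loci at 1 (S100a4) and 0 of 18 (0.489), chondrocyte loci at 1 and 2 of 6 (0.489), and smooth muscle loci at 0 and 2 of 5 (0.121). AP-1 loci fell at 3 of 21 (Atf3, Fos, Fosb; 0.475), interferon loci at 2 of 12 (0.563), senescence loci at 2 of 8 (0.761), erythroid and megakaryocyte loci at 2 of 7 (0.160) and ubiquitously open loci at 2 of 14 (0.875). Pan-haematopoietic loci rose at 1 and fell at 3 of 13 (0.301). A single locus rose in the cell cycle (0.994), myeloid (0.652), endothelial (0.244, but 0.0426 with all deposited peaks), Schwann (0.563) and other-organ lists (0.151), and none passed in the adipocyte (0.489), unfolded protein (0.761) and transduced lists (0.761).

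Genome-wide, 568 loci rose and 614 fell in control cultures, 1182 together, and this total was 586 to 671 when any 1 Scf-GFP-positive or control library was left out (586 without Scf-GFP-positive replicate 1, 671 without control replicate 3). Regions open in all control and no Scf-GFP-positive libraries numbered 8934, and the reverse 7484. The reverse number was 15306 without Scf-GFP-positive replicate 1 and 15253 without replicate 2.

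The transduced genes were the target of the rMSC, and peaks covered more of 2 of the 5 loci, Irf3 and Irf7, than in control cultures. Irf3, an interferon response regulator (chromosome 7, 44997648 to 45002848), went from 1.33 to 4.67 ± 1.53 summits (log2 1.49 ± 0.32, adjusted p = 0.0502, n = 3 and 3), just short of the threshold, and passed when adjusted over the list of 5 alone. With all deposited peaks counted, peaks covered 11.7 ± 1.87% of its gene body in control cultures and 52.4 ± 3.97% in rMSC, and 25.5 ± 1.83% and 61.1 ± 26.4% of Irf7 (one-sided exact p = 0.05 each, the smallest possible). With equal-size lists the shares were 9.84% and 49.0% at Irf3 and 20.5% and 61.1% at Irf7. At Irf7 the number of summits did not pass (log2 0.49 ± 0.36, adjusted p = 0.540). Coverage of Irf7 in rMSC also overlapped that of untransduced stroma. It was 35.2% in rMSC replicate 1, and 37.2% and 51.4% in Scf-GFP-negative replicates 1 and 2. Coverage did not rise at Klf7 (3.21% and 2.97%, exact p = 0.65), Ostf1 (6.45% and 7.15%, exact p = 0.3) or Xbp1 (29.4% in both, exact p = 0.5). Copies of the transduced sequence could also give peaks inside these gene bodies, and this was left undecided. The values therefore do not show that the cells' own Irf3 and Irf7 loci opened. Whether any of the 5 factors was made as protein was not analysed here.

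Timp3, an inhibitor of matrix proteases (chromosome 10, 86300412 to 86349505), rose from 8.00 ± 1.00 to 26.0 ± 4.58 summits (log2 1.63 ± 0.15, adjusted p = 0.00318). Cadps, a vesicle release gene (chromosome 14, 12372560 to 12823339), had 5, 8 and 9 summits in rMSC and none in any other library (adjusted p = 0.00571). Pdgfd, a growth factor gene, rose from 0 to 4.33 ± 1.15 summits (adjusted p = 0.00178) and Col13a1, a membrane collagen gene on chromosome 10, from 0 to 3.67 ± 1.53 (adjusted p = 0.00665). Xylt1, which starts proteoglycan chains (chromosome 7, 117380979 to 117667630), lost all of 9.67 ± 3.06 summits (adjusted p = 0.0012). Tiam1 lost all of 7.0 ± 1.00, the protease gene Adamts16 fell from 12.0 ± 1.73 to 0.333 (log2 −4.11 ± 0.40, adjusted p = 0.0048) and Pcdh7 from 10.0 ± 1.00 to 0.667 (log2 −3.33 ± 0.40, adjusted p = 0.00887). These 8 and Gda were the only named loci that kept the call in every left-out fit that tested them. With any of the rMSC libraries left out, 24 of 27 passing loci were tested. Cadps was among those below the summit filter, so these fits did not test its call. Ebf1 fell by log2 0.88 ± 0.14 (adjusted p = 0.0218), but not without control replicate 1 (adjusted p = 0.0615) or rMSC replicates 2 (0.0671) or 3 (0.0633). Dpp10 rose from 0 to 10.0 ± 2.65 summits (adjusted p = 0.0229), with adjusted p from 0.0671 to 0.0814 without any of 6 libraries.

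No gene list separated rMSC from control cultures. The lowest list adjusted p was 0.446, for the mesenchymal (Ebf1 fell), interferon (Parp14 rose by log2 1.22 ± 0.25, Ifih1 fell by 0.65), smooth muscle (Tbx18 rose) and Schwann lists, the last without a passing locus. Phex fell among osteoblast loci (list adjusted p = 0.832), Timp3 rose among fibroblast loci (0.992), Rb1 rose among senescence loci (0.558) and Ebf1 was the only change among pan-haematopoietic loci (0.832). No member passed genome-wide in the transduced (0.558), niche factor (0.992), adipocyte (0.793), chondrocyte (0.558), unfolded protein (0.832), AP-1 (0.992), cell cycle (0.952), myeloid (0.832), erythroid and megakaryocyte (0.800), endothelial (0.952), ubiquitously open (0.992) and other-organ lists (0.686). Adjusted over the list alone, transduced genes rose at 1, interferon loci rose at 3 and fell at 1, and chondrocyte loci rose at 1 and fell at 1. In the same way osteoblast loci rose at 1 and fell at 2, mesenchymal loci fell at 2 and adipocyte loci fell at 1. Kitl (log2 −0.47, adjusted p = 0.715) and Cxcl12 (−0.28, adjusted p = 0.786) did not change detectably. Genome-wide, 182 loci rose and 133 fell, 315 together, and the total was 90 without control replicate 1, 93 without rMSC replicate 2 and 589 without Scf-GFP-negative replicate 2. Of the 182 rising loci 59 lie on chromosomes 10 and 15, 32.4% against 10.5% of tested loci, because rMSC have more peaks over all of these chromosomes. After chromosome totals were equalised 116 loci rose, 16 of them there, and the falling loci went from 133 to 95. Lists of equal size also tie the chromosomes together. Of 224 bins of 10 Mb outside chromosomes 4, 10 and 15, 78 had a lower and 18 a higher share in every rMSC than in every control library. Every rMSC library shares the excess on chromosomes 10 and 15, so effects of the transduced genes cannot be told apart from another change common to the rMSC cultures.

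Regions open in all rMSC and no control libraries numbered 3877, and the reverse 4383. The strongest in rMSC lay 1035 bp from Trip10 (chromosome 17, 57264732 to 57265698, also open in all 4 sorted libraries), 11087 bp from Defb3 (chromosome 8, 19280635 to 19282274) and 187379 bp from Prdm1 (chromosome 10, 44715937 to 44717592). The strongest in control cultures lay in Plekha2 (chromosome 8, 25069769 to 25071652), in 1110051M20Rik (chromosome 2, 91312371 to 91313802) and 62069 bp from the glucocorticoid receptor gene Nr3c1 (chromosome 18, 39581490 to 39582685). The first 2 were also open in both Scf-GFP-positive libraries.

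Control cultures and rMSC differed at regions that separate culture from freshly sorted stroma, without a shown return of rMSC toward the latter. Of regions with peaks in Scf-GFP-positive stroma and none in 2 control libraries, 7.42 ± 1.01% were open in the left-out control library and 13.2 ± 0.432% in rMSC (exact p = 0.1, the smallest possible, n = 3 and 3). Of regions gained in 2 control libraries, 81.5 ± 2.03% were open in the left-out control and 52.9 ± 1.01% in rMSC (exact p = 0.1). Regions chosen on control libraries favour this direction, and the mirror choice on rMSC reversed both differences. Of lost regions 5.56 ± 0.297% were then open in the left-out rMSC library and 20.7 ± 0.883% in control cultures, and of gained regions 82.5 ± 1.06% and 50.8 ± 1.27%. The shares therefore show only that the cultures differ. Similarity to Scf-GFP-positive stroma, which needs no choice of regions, was 0.344 ± 0.0113 in control cultures and 0.331 ± 0.0022 in rMSC (difference −0.0135, exact p = 0.1), and the difference was −0.00697 without control replicate 3.

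Against freshly sorted Scf-GFP-positive stroma, rMSC had fewer summits at some bone loci. Alpl lost all of 9.50 ± 0.707 summits, and the osteoblast list fell at 3 of 8 loci (Col1a1, Alpl, Pth1r) and rose at 0, with 5 falling adjusted over the list alone (list adjusted p = 0.00219, but with an estimated correlation adjusted p = 0.179). Pth1r fell by log2 1.69 ± 0.30 (adjusted p = 0.0125), but not without Scf-GFP-positive replicate 1 (adjusted p = 0.0677) or 2 (0.0526). St3gal6 (log2 −4.17 ± 0.45, adjusted p = 0.00209) and Sema4d (−4.16 ± 0.45) also had far fewer summits, with 0.333 on average in rMSC and none in control cultures, and Bcl11a, Car3 and Ikzf1 had no summit. Adcy2 lost all of 10.0 summits. Cadps opened, as did Trpm6, from 0 to 6.33 ± 0.577 summits, and Ptprr on chromosome 10, from 0 to 7.0 ± 1.00. Timp3 rose by log2 2.01 ± 0.16 (adjusted p = 0.000662), Mcm6 by 1.34 ± 0.19 (adjusted p = 0.0053) and Irf3 by 1.37 ± 0.35 (adjusted p = 0.0419, but 0.199 without Scf-GFP-positive replicate 2). For Irf3, copies of the transduced sequence are undecided here as well. Zeb2 fell by 1.36 ± 0.20 (adjusted p = 0.00676). Kitl (log2 −0.06, adjusted p = 0.996) and Cxcl12 (−0.08, adjusted p = 0.954) did not change detectably.

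The other lists did not pass in this comparison. Niche factors rose at 1 (Thpo) and fell at 0 of 16 (list adjusted p = 0.983), mesenchymal loci at 0 and 3 of 17 (Prrx1, Ebf1, Zeb2; 0.686), fibroblast loci at 3 and 1 of 18 (0.485), interferon loci at 1 and 2 of 12 (0.983), AP-1 loci at 1 and 1 of 21 (0.331), adipocyte loci at 0 and 1 of 7 (Zfp423; 0.288, but 0.0261 with all deposited peaks), smooth muscle loci at 0 and 2 of 5 (0.331), Schwann loci at 1 and 0 of 8 (0.130), pan-haematopoietic loci at 1 and 4 of 13 (0.126, but 0.0261 with all deposited peaks), erythroid and megakaryocyte loci at 0 and 2 of 7 (0.122) and transduced genes at 1 and 0 of 5 (0.853). A single locus rose in the cell cycle (0.983), myeloid (0.983) and endothelial lists (0.331), 1 fell among ubiquitously open loci (0.983), and none passed genome-wide in the chondrocyte (0.983), unfolded protein (0.983), senescence (0.983) and other-organ lists (0.288). Adjusted over the list alone, 2 chondrocyte loci fell and 1 other-organ locus rose. Genome-wide, 686 loci rose and 623 fell, 1309 together, and the total was 638 without Scf-GFP-positive replicate 1. Of the rising loci 127 lie on chromosomes 10 and 15, and 61 of 713 after chromosome totals were equalised. Regions open in all rMSC and no Scf-GFP-positive libraries numbered 9858, and the reverse 8563, or 16379 and 16662 without Scf-GFP-positive replicate 1 or 2.

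**Figure D3:**
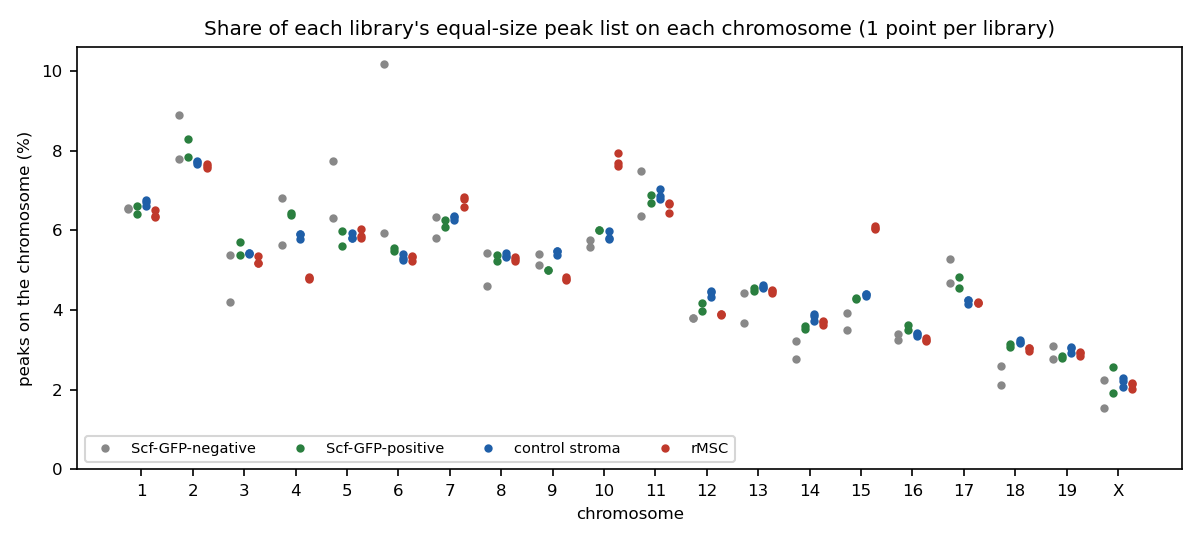
Share of each equal-size peak list on every chromosome, 1 point per library.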

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

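The groupings named here came from a scan made after the data were seen, and no test was chosen for them. Peaks on chromosome Y were set aside from every comparison. They numbered 24.28 per 10000 peaks in Scf-GFP-negative replicate 1, 6.01 in Scf-GFP-negative replicate 2 and 9.858 in Scf-GFP-positive replicate 1. The remaining libraries had fewer, with 3.66 in Scf-GFP-positive replicate 2, 3.718 at most in control cultures and 2.421 to 3.017 in rMSC. Groups of 2 or 3 libraries are too small for an outlier test. The sex of the donors was not used here.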

How the results depend on the processing

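The windows within 5 kb of either gene end, the equalised chromosome totals, the regions over 1 kb from gene ends, the results without chromosomes 4, 10 and 15, the culture regions chosen on rMSC and the coverage of the transduced genes were chosen after seeing the data, and the other alternatives before. Motif shares and exon peaks were not run. For Scf-GFP-positive against Scf-GFP-negative stroma the 2863 changed loci became 5203 with 50 kb windows, 809 at gene ends and 1063 with only the 2 groups fitted. For control cultures against Scf-GFP-positive stroma 1182 became 2066 with 50 kb windows, 279 at gene ends, 1892 without a filter, 429 with the replicate number as a block, and 586 (without Scf-GFP-positive replicate 1) to 1465 (without Scf-GFP-negative replicate 1) with a library left out. For rMSC against control cultures 315 became 509 with 50 kb windows, 93 at gene ends, 829 without a filter, 53 with the block, and 90 (without control replicate 1) to 589 (without Scf-GFP-negative replicate 2). For rMSC against Scf-GFP-positive stroma 1309 became 2609, 315, 2425 and 639 in the same order, and 638 to 1679 with a library left out. Of same-number pairs 0 of 13 correlated over 0.1. Counts per locus are low, and with 2 libraries in a group their deviations mirror each other. The correlations therefore cannot tell whether replicate numbers pair the libraries, and the lower numbers with the block stand as a limit. Regions of Scf-GFP-positive over Scf-GFP-negative stroma were 12210 to 20067 without 1 library, and the reverse was 3316 with the stricter threshold and 6663 to 19937 without 1 library. Regions of control cultures over Scf-GFP-positive stroma were 13632 with all peaks, and the reverse 7998 to 15306 without 1 library. Those of rMSC were 17402 with all peaks, and the reverse 9044 to 16662 without 1 library. The culture-lost difference was 4.762 points with the stricter threshold and 4.000 to 5.988 with a library left out, and with at least 50% of a region covered its exact p was 0.3. The culture-gained difference was −21.15 with all peaks, −26.97 with the stricter threshold and −20.07 to −28.98 with a library left out. With regions chosen on rMSC the 2 differences reversed to −15.12 and 31.7. Of the lists called for Scf-GFP-positive against Scf-GFP-negative stroma, cell cycle lost its call in 9 alternatives, mesenchymal in 3 and smooth muscle in 2, and the osteoblast list lost it in 4 for control cultures and 3 for rMSC against Scf-GFP-positive stroma.

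Of the 215 named pairs that passed, 207 kept their sign in every alternative that tested them. At gene ends 29 of 38, 9 of 19, 0 of 6 and 11 of 22 tested passing loci of the 4 comparisons still passed. With only the 2 groups fitted, 30 of 80, 30 of 48, 13 of 22 and 33 of 45 still passed. With the block, 78 of 85, 32 of 54, 9 of 27 and 33 of 49 did. For Scf-GFP-positive against Scf-GFP-negative stroma the sign changed, also counting named pairs that did not pass, with 50 kb windows at Comp (−1.01), Edem1 (−0.38), Ier3 (0.0451), Cd68 (0.12), Klf7 (0.64), Ostf1 (−0.27), Xbp1 (−0.77) and Irf3 (0.11). It changed with the stricter threshold at Egr1 (−0.13) and Xbp1 (−0.00798), at gene ends at Klf7 (0.18) and Angpt1 (0.65), with all peaks at Xbp1 (−0.40) and Irf3 (0.0246), and without Scf-GFP-positive replicate 2 at Klf7 (0.0243, against −0.63 without replicate 1). For control cultures against Scf-GFP-positive stroma it changed with 50 kb windows at Ermap (0.28), Ostf1 (−0.0803), Xbp1 (0.42) and Irf3 (0.12), with the stricter threshold at Ostf1 (−0.16) and with all peaks at Kitl (−0.21). It also changed without control replicate 3 at Xbp1 (0.24), without Scf-GFP-positive replicate 1 at Irf3 (0.25, against −0.49 without replicate 2) and Cxcl12 (−0.0410, against 0.44), and without replicate 2 at Kitl (−0.47, against 1.30 without replicate 1). For rMSC against control cultures it changed with all peaks at Irf7 (−0.16) and Kitl (0.39), without control replicate 1 (−0.0410) or rMSC replicate 3 (−0.0809) at Klf7 (0.34 at the highest), and without control replicate 3 at Xbp1 (−0.0809, with 0.33 at the highest). For rMSC against Scf-GFP-positive stroma it changed with 50 kb windows at Thpo (−0.34), Ermap (0.16), Ostf1 (−0.0803), Irf7 (0.00576) and Kitl (0.24), with the stricter threshold at Xbp1 (−0.18) and Irf7 (0.19), with all peaks at Kitl (0.18) and Cxcl12 (0.64), and with the flow cell as covariate at Kitl (0.0680). Without Scf-GFP-positive replicate 2 it changed at Irf7 (0.16) and Cxcl12 (0.16), against −0.32 at both without replicate 1, and for Kitl it changed without Scf-GFP-positive replicate 1 (0.82) or rMSC replicate 2 (0.11), against −0.94 without Scf-GFP-positive replicate 2.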

Other observations

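All patterns weighed here were found and tested on the same data, so they remain hypotheses. The predictions for the gene cluster test and for the gene splits were fixed after seeing the data, and the other predictions before. The always-open regions were first compared after centring each region on its mean over the libraries. The uncentred form given here was adopted after that result was seen, and it led to the same labels.

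In rMSC, chromosomes 10 and 15 held 7.75 ± 0.182% and 6.07 ± 0.0468% of equal-size lists, against 5.87 ± 0.108% and 4.39 ± 0.0308% in control cultures, and chromosome 4 held 4.81 ± 0.0327% against 5.87 ± 0.0818% (exact p = 0.1 each). At regions open in all 10 libraries the median log2 fold of chromosome 10, relative to the other chromosomes, lay 0.6384 higher in rMSC (centred 0.5956), that of chromosome 15 lay 0.4414 higher (centred 0.4546) and that of chromosome 4 differed by −0.2803 (centred −0.2766), without overlap. Such shifts were predicted for extra copies of chromosomes 10 and 15 and fewer of chromosome 4 in the rMSC cultures. Every rMSC library carried them (chromosome 10 at 0.6464, 0.6698 and 0.7303) and no control library did. A change common to the rMSC cultures therefore cannot be told apart from effects of the transduced genes, and the libraries may not be independent. Longer lists are excluded, since with equal sizes the difference on chromosome 10 was 17.52 SD of the control libraries, and so are a few gene clusters, since 100% of the 24 bins of 10 Mb with enough peaks to count rose on both chromosomes. The last bin of chromosome 10 had too few peaks to count. Smaller shifts without overlap occurred on chromosomes 9 (−0.112), 12 (−0.165) and X (0.0981).

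Scf-GFP-negative replicate 1 had 11.83% of its weaker peaks on chromosome 6, against 5.974% in replicate 2. Among the 10000 strongest peaks the share was 1.024 times that of replicate 2, which is in line with an excess near the caller's threshold. The median fold at regions open everywhere differed by 0.01053 (centred 0.0438), which argues against a copy number change shared by all cells of replicate 1. A change in part of the cells could be too small for this test to see.

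The extra Irf3 summits in rMSC lay inside the gene body (with all deposited peaks 4.67 against 1.00 in control cultures, with equal-size lists 4.00 against 0.667), and its flanks did not change (0.667 in both groups for both lists). Against control cultures, coverage of the gene body rose without overlap at 2 of the 5 transduced genes, which leaves copies of the transduced sequence undecided. The measure is insensitive for the long genes Klf7 and Ostf1.

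Only 1 of the 10 splits of the 6 cultured libraries, the real one, gave 315 changed loci (highest other 0) and 8260 regions (highest other 367), but 10 splits are too few to decide. Of 100 splits of sorted against cultured libraries 1, the real one, gave 4847 regions (highest other 516). The other splits break up the 4 groups, so this does not separate a sorted and a cultured class from the likeness of replicates.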
